A study of Homo sapiens with 6 samples.

How the data were processed

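RNA of 2 human cell lines, NP69 and C666-1, was measured on 6 1-colour Affymetrix arrays (biotin label, 250 ng RNA per array), 4 of NP69 (control, LPS, PGN and streptoc) and 2 of C666-1 (control and streptoc), 1 array per group, after culture at 37 °C and 5% CO2, per the labels. The design text of the series speaks of LPS and PGN for both lines, whereas the sample labels give C666-1 streptoc alone, and the sample labels were followed. Dose, time and the meaning of streptoc are not given in the sources used here.

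The deposited values are on the log2 scale, to 2 decimals, for 54613 probes. They were made by robust multi-array average (RMA), per the submitters' processing notes, and the software and its version are not given in the sources used here. The log2 scale was read from the range of the deposited values. No further normalization was applied. The number of arrays limits the precision, and no error within a group could be estimated.

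Probes with exactly 1 gene symbol (41091) were used, and 1801 with several symbols and 11721 without a listed gene were left out. Of the probes used, 41037 matched a current symbol by Entrez ID in the human RefSeq gene table (assembly GRCh38.p14) and 0 symbols were updated. A gene with over 1 probe (10523 of 19775 genes) took the probe with the highest mean over the 6 arrays. Genes were kept where the highest of the 6 values was at or above the median of all values of these probes, 4.92, which left 13430 and took out 6345.

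The differences of log2 values per gene were taken for 6 pairs of arrays, along with the difference of the 2 streptoc effects, and genes with a difference of at least 1 (2-fold) in either direction were counted. No test was run on single pairs of arrays. Fixed lists (28 lists, 836 genes, 746 on the array with a single name and 626 kept) were described by the median difference and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called higher above percentile 97.5 with a median above 0, and lower below percentile 2.5 with a median below 0. Each percentile describes these arrays and is not a p-value. Calls were repeated after subtraction of a loess curve (span 0.3) of the difference on mean expression. For the 3 NP69 treatments, which share 1 control array, correlations and covariances across genes were set beside 100 simulated sets of unchanged arrays, and overlaps beside those of independent lists.

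The lists, the comparisons, the thresholds and the rule for named genes were fixed before the data were examined. That rule takes the 8 highest and 8 lowest genes past 2-fold per pair of arrays, the 3 members furthest in the direction of the median in each list outside its percentiles, the 5 leading genes shared by the 3 NP69 treatments or by streptoc in both lines, the 5 per sign with the largest difference between the streptoc effects, and a short set of fixed genes.

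Alternatives chosen at the same time were no filter, a filter at the 75th percentile (6.68), a 1.5-fold threshold, arrays centred on the median of their kept genes, subtraction of the loess curve, the mean of all probes of a gene, the mean of the other 3 NP69 arrays as reference, and 2 limma models (line and streptoc on 4 arrays, with 1 residual degree of freedom, and line on all 6 arrays) with Benjamini-Hochberg adjusted p below 0.05. Added after seeing the data were quantile normalization, only probes whose type is unmarked (no s, x or a), the LPS array as reference, the C666-1 streptoc difference minus its regression on the LPS difference, and line comparisons between arrays of like spread.

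The computations were tested on simulated data. For NP69 streptoc minus control, 200 of 13430 genes were changed, with noise of SD 0.12 per array. Of the genes changed by 1.5 and by 3, 100% and 100% were recovered, with 0 false calls. This noise was even across genes and had no trend with expression, whereas the observed differences of this pair had a robust SD of 0.43. The 0 false calls check the computation and give no error rate for the real counts. In the limma model of streptoc on 4 arrays (13430 genes, noise of SD 0.2), 98% of the genes changed by 1 and 100% of those changed by 2 were recovered, with 9 false calls (4.3% of calls). In the model of line on 6 arrays (13430 genes) the shares were 99% and 100%, with 15 false calls (7%). Both limma simulations had even noise across genes, and the simulated streptoc change was the same in both lines. The real streptoc differences of the 2 lines disagreed, so these shares check the computation and give no recovery rate for the real arrays. Of 40 random lists 3 lay outside the percentiles, and 40 of 40 lists shifted by 0.25 were found.

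Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.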

Results

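Expression was measured on 6 arrays from 2 human cell lines. NP69 is an immortalised line from normal nasopharyngeal epithelium, and C666-1 is a line from nasopharyngeal carcinoma, a tumour of the same epithelium. NP69 was profiled untreated and after co-culture with agents labelled LPS, PGN and streptoc, and C666-1 was profiled untreated and after co-culture with streptoc. LPS and PGN are the usual abbreviations of lipopolysaccharide and peptidoglycan, 2 bacterial cell wall components, and the labels do not spell out any of the 3 names or give a dose or time. Each of the 6 groups had 1 array, so no difference below has a replicate check and no error within a group could be estimated. Values are log2 expression, and a difference of 1 is a 2-fold difference. Of 19775 genes with a probe of their own, 13430 passed the filter on low values (4.92 on at least 1 array) and were compared.

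The arrays differed in the spread of their values. The distance between the 10th and 90th percentiles of all probes was 5.05 on the NP69 control array and 5.14 on the C666-1 streptoc array, against 5.30 to 5.45 on the other 4. The median of the compared genes was likewise 6.71 and 6.74 on these 2 arrays and 6.84 to 6.89 on the others. Every difference of a treatment from the control of its line includes 1 of these 2 arrays. Highly expressed genes therefore tended to differ from 0 upwards in the NP69 treatments and downwards in C666-1 with streptoc. In genes with a mean expression of 7.83 to 8.48, the median difference was 0.13 with LPS, 0.15 with PGN, 0.22 with streptoc in NP69 and -0.19 with streptoc in C666-1. Gene lists were for that reason set against random lists of the same size and expression.

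**Figure D1:**
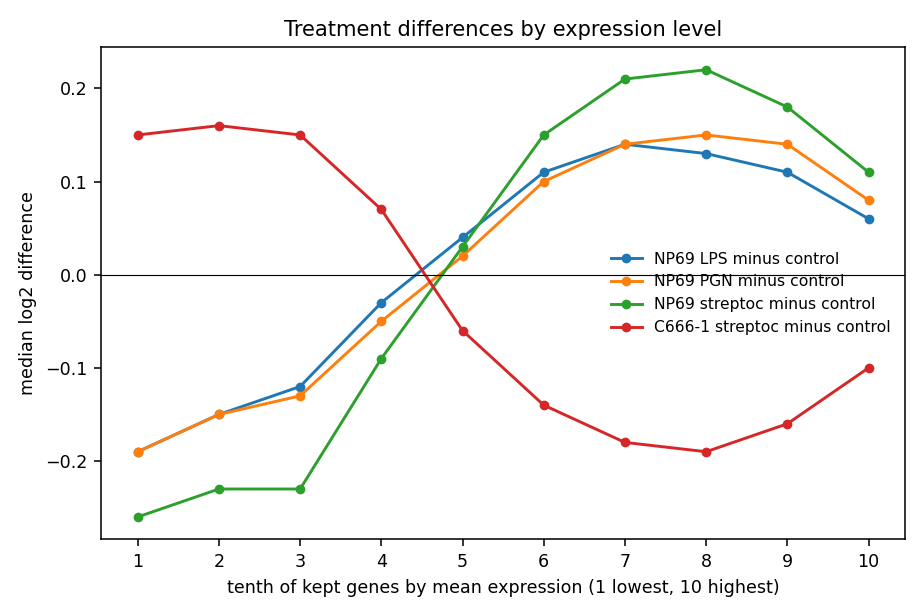
Median log2 difference from the untreated array of the same line (y axis) in groups of 1343 of the 13430 compared genes by mean expression over the 6 arrays (x axis), 1 line per treatment. The 3 NP69 treatments run from -0.19 or -0.26 in the lowest group to a highest value of 0.14 to 0.22, and C666-1 with streptoc runs the opposite way, from 0.15 to -0.10.

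The first question was how NP69 cells differed from untreated cells with LPS. The differences were small, and none reached 4-fold. The NF-kB targets, which encode cytokines, chemokines and feedback inhibitors of inflammatory signalling, had 2 of 30 measured members higher by 2-fold, CXCL8 (1.18) and TNFAIP2, and a median of 0.03 inside their random lists (percentile 57.67). After removal of the trend with expression the list was called higher, with a median of 0.13 (percentile 97.81). CXCL8, a neutrophil-attracting chemokine, was 3.45 in the control and 4.63 with LPS, both below the filter value, and its other probe gave a difference of 0.43. IL6 was 5.79 and 6.66. CCL20 (-0.36), IL1B (-0.40) and TNF (-0.21) were not higher. Interferon-stimulated genes and genes of the cornified envelope, the outer protein layer of squamous epithelium, were lower.

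Across the interferon-stimulated list, 28 of 37 members were below the control, 3 of them by 2-fold, with a median of -0.21 (percentile 0 of random lists). IFI27 had a difference of -1.56, IFI6 of -1.44 and CXCL10, a chemokine induced by interferon, of -1.33. Of 27 cornified envelope genes 21 were below the control and 2 passed 2-fold, with a median of -0.26. SBSN (-1.51) and KRTDAP (-1.47), both made by differentiating squamous cells, were lowest, followed by the keratin KRT1 (-0.93). Cell cycle genes lay slightly above their random lists. All 33 S phase genes were above the control (median 0.23), led by CCNE2 (0.72) and RRM2 (0.70), and 27 of 34 mitosis genes were (median 0.28), led by KIF11 (0.82). None of these 67 genes passed 2-fold. The p53 target list had a median of 0.27 and 1 of 24 members past 2-fold, PLK2 (1.03). The mesenchymal and matrix list had a median of 0.19, with COL12A1 (1.13) past 2-fold and FN1 at 0.85, and of -0.05 without the filter on low values. ER stress and amino acid response genes (median 0.20, HERPUD1 0.75) and NRF2 targets (median 0.21, TXNRD1 0.69) were also called higher, with no member past 2-fold. Both of these last 2 calls ended after removal of the trend with expression, at percentiles 96.5 and 96.37.

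In all, 90 genes were higher and 6 lower by 2-fold with LPS. The genes furthest above the control were PSMA3-AS1 (1.91), ALDH1L2 (1.60), KCNJ16 (1.56), NEDD9 (1.51), EPS8 (1.5), ZC3H12C (1.45), RCBTB1 (1.45) and MDM1 (1.44). All of these but RCBTB1 (5.21) and MDM1 (5.33) were below the filter value in the control, at 4.20 (ALDH1L2) to 4.79 (KCNJ16). With LPS they were above it. A second probe of PSMA3-AS1 gave -0.04. With each array centred on its median, which moved every difference by -0.13, the split was 38 higher and 17 lower, and with the mean of all probes per gene it was 26 and 5. Set against the mean of the other 3 NP69 arrays (control, PGN and streptoc), LPS had 0 genes higher and 38 lower. That mean is mostly of treated arrays, so this split answers another question than the control alone.

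With PGN, NP69 cells had higher levels of inflammatory cytokines and chemokines than untreated cells. Of the 30 NF-kB targets 15 were higher by 2-fold and 0 lower, and the list median was 1.05 (percentile 100). CXCL8 was 9.25 against 3.45 in the control, a difference of 5.80. The chemokines CXCL2 (4.12), CXCL1 (3.63), CCL2 (3.41) and CCL20 (3.37), the cytokine IL6 (3.70) and the feedback inhibitor TNFAIP3 (2.96) followed. NFKBIA, the inhibitor that NF-kB itself induces, differed by 1.69, IL1B by 0.75 and TNF by -0.39.

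Immediate early genes, which respond to signals without new protein synthesis, had 7 of 30 members higher by 2-fold and a median of 0.56. Among them were DUSP5 (1.60), KLF4 (1.5) and KLF10 (1.26). The small MAF protein gene MAFF, outside the lists, was 2.83 higher, or 0.60 by another probe. The p53 target list had a median of 0.33 with PLK2 (1.57) and PMAIP1 (1.02) past 2-fold. S phase genes had a median of 0.26, with RRM2 at 0.87, CCNE2 at 0.82 and DTL at 0.65, and none past 2-fold. As with LPS, interferon-stimulated genes (median -0.13, 3 of 37 lower by 2-fold) and cornified envelope genes (median -0.23, 3 of 27 lower and 1 higher) lay below their random lists. SBSN (-1.71), KRTDAP (-1.48), IFI6 (-1.28), IFI27 (-1.19), IRF9 (-1.15) and KRT1 (-1.13) were lowest, along with GPNMB (-1.24) and DGKK (-1.06). After removal of the expression trend KRT1 (-0.96) and DGKK (-0.89) were short of 2-fold.

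In all, 226 genes were higher and 11 lower by 2-fold with PGN, and 19 of the higher ones passed 4-fold. With each array centred on its median, a shift of -0.13, the numbers were 139 and 20, with the mean of all probes per gene 106 and 10, and against the mean of the other 3 NP69 arrays 14 and 3. Against the LPS array in place of the control, an alternative chosen after seeing the data, 46 genes were higher and 0 lower. Of the 46, 41 were among the 226. The NF-kB median was then 1.12 and the immediate early median 0.395, both at percentile 100. Inside their random lists lay p53 targets (0.065), S phase (-0.01), cornified envelope (0) and interferon-stimulated genes (0.05). An effect shared with LPS and a control array standing apart would both give this.

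Streptoc gave the largest treatment differences in NP69. Of the 30 NF-kB targets 19 were higher by 2-fold and 1 was lower, with a median of 2.05 (percentile 100). CXCL8 reached 11.08, 7.63 above the control, and CCL2 (6.03), CXCL2 (5.63), CXCL1 (5.54), CCL20 (5.45), IL6 (4.95) and IL1A (4.89) were among the 8 highest genes. PTX3, a secreted pattern recognition protein outside the list, was 5.52 higher. TNFAIP3 differed by 4.32, NFKBIA by 2.37 and IL1B by 2.13, whereas TNF (-0.15) was not higher. The chemokine CX3CL1 was lower (-1.04, or -0.84 after removal of the expression trend).

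Several stress lists were called higher with streptoc. Of 24 NRF2 targets, the antioxidant and detoxification genes, 9 were higher by 2-fold, with a median of 0.70, and 0 had been so with LPS or PGN. They included HMOX1 (2.19), which degrades haem, GCLM (1.90), which makes glutathione precursors, and AKR1C3 (1.74). The hypoxia and glycolysis list had 7 of 30 members higher and a median of 0.29, with ADM (3.02), ANKRD37 (2.05) and VEGFA (1.99) leading. The immediate early list had 14 of 30 higher (median 0.88), led by DUSP5 (3.03), FOSL1 (2.96) and ATF3 (2.40). The ATF3 value rests on 1 of its probes, and another probe gave -0.31, and another probe of VEGFA gave 0.11. The p53 target list had a median of 0.47, with PMAIP1 (2.24), PLK2 (1.94) and CDKN1A (1.49), an inhibitor of cyclin-dependent kinases, past 2-fold.

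Cornified envelope and interferon-stimulated genes, lower with LPS and PGN, were not called lower with streptoc. Cornified envelope genes had a median of 0.26, with SERPINB4 (2.58) and SERPINB3 (1.17) past 2-fold and SPRR3 at 0.87. Interferon-stimulated genes had a median of 0.06, inside the random lists, and CXCL10 was 7.92 against 6.52 in the control. The antimicrobial list had 3 of 19 members higher, the S100 proteins S100A9 (1.28), S100A8 (1.22) and S100A7 (1.11), with a median of 0.20. Its call ended after removal of the expression trend (percentile 96.36), although the median was then still 0.175. Mesenchymal and matrix genes had a median of 0.25 with TNC (2.20) and LOX (2.06) past 2-fold and COL12A1 at 0.90, and a median of -0.05 without the filter on low values. Heat shock genes (median 0.29, CHORDC1 1.26) and 11 histone genes (median 0.40, H2BC5 0.69) were called higher. Mitosis genes had a median of -0.07, below their random lists, with AURKA at -0.58 and CDC20 at -0.52 and none past 2-fold. MHC class II genes had a median of -0.35 (HLA-DMB -0.58, HLA-DOB -0.57, HLA-DRA -0.56), a call that ended after removal of the expression trend (percentile 6.74).

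In all, 525 genes were higher and 13 lower by 2-fold, and 70 of the higher ones passed 4-fold. The lowest were CCDC197 (-1.30), GAS1 (-1.25), TSC22D3 (-1.20), a target of glucocorticoids, NANOG (-1.10), PRR15L (-1.06), CYSLTR2 (-1.05), CX3CL1 and HOXD9 (-1.04). After removal of the expression trend NANOG (-0.84), CYSLTR2 (-0.78), CX3CL1 (-0.84) and HOXD9 (-0.95) were short of 2-fold. With each array centred on its median, a shift of -0.18, the split was 317 higher and 109 lower, with the mean of all probes 280 and 4, and against the mean of the other 3 NP69 arrays 191 and 3. Against the LPS array in place of the control, an alternative chosen after seeing the data, 213 were higher and 11 lower. Of the 213, 187 were among the 525, and the NF-kB median was 1.89. The antimicrobial (-0.06, percentile 25.82) and mesenchymal (0.06, 87.1) medians then lay inside their random lists. The p53 median shrank to 0.215 (99.8), and the other lists called with streptoc stayed outside theirs in the same direction.

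**Figure D2:**
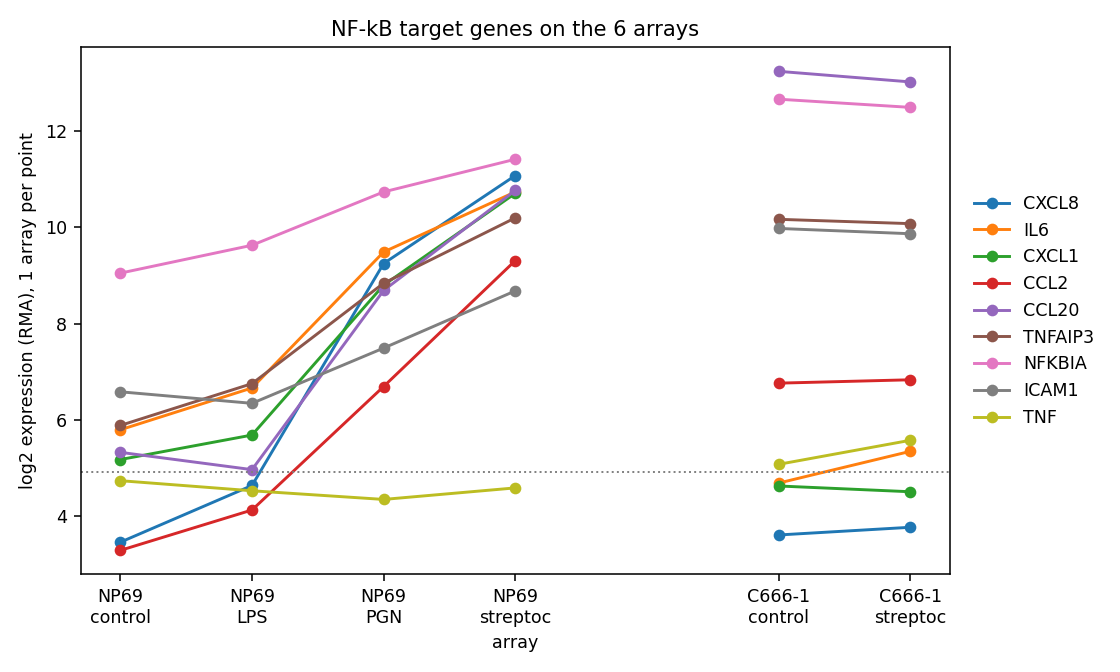
Log2 expression (y axis) of 9 NF-kB target genes on each of the 6 arrays (x axis), 1 array per point, with lines joining the arrays of a line only to guide the eye and the filter value of 4.92 dotted. In NP69 CXCL8 stands at 3.45, 4.63, 9.25 and 11.08 in the control, LPS, PGN and streptoc arrays, and in C666-1 at 3.60 and 3.76, while CCL20 and NFKBIA are above 12 on both C666-1 arrays.

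The 3 NP69 treatments, all set against the same control array, shared part of their higher genes. LPS and PGN had 63 higher genes in common, where independent lists would share 1.51, LPS and streptoc 61 (3.52) and PGN and streptoc 183 (8.83). Simulated unchanged arrays against 1 control, with noise taken from the LPS and PGN arrays, shared 0.01 genes in the mean of 100 sets, a value that leaves out a control array standing apart from the others. A gene low on that array alone would enter all 3 lists, so part of these overlaps may come from it. In all 3 treatments 49 genes were higher by 2-fold and 0 lower. KCNJ16 (1.56, 1.54 and 1.76 with LPS, PGN and streptoc), NEDD9 (1.51, 1.54 and 2.31), ZC3H12C (1.45, 2.25 and 2.94), BBS7 (1.35, 1.44 and 1.53) and PSMA3-AS1 (1.91, 1.53 and 1.64) led these. These leading genes all lay below the filter value on the control array, at 4.37 (NEDD9) to 4.79 (KCNJ16), and above it on the 3 treated arrays. Each of their differences thus rests on 1 low control value. Another probe gave 0.06, 0.13 and 0.10 for NEDD9 and -0.04, -0.08 and -0.06 for PSMA3-AS1. CXCL8 was also among the 49. Of the 226 genes higher with PGN, 158 were higher still with streptoc, and 134 were past 2-fold with both PGN and streptoc but within 2-fold with LPS. IFI27, IFI6, SBSN and KRTDAP were lower by 2-fold with both LPS and PGN.

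Because the 3 differences share the control array, correlations between them lie above 0 without any effect. Across genes, which are not independent replicates, Pearson's r was 0.823 for LPS and PGN, 0.687 for LPS and streptoc and 0.838 for PGN and streptoc, where simulated unchanged arrays gave 0.5. The covariances were 0.0996, 0.1111 and 0.1571 against a simulated 0.0226. With 1 control array the controls could not be split, and part of the excess may come from that array. Pairs of differences without a shared array gave 0.128 (LPS minus control with streptoc minus PGN), 0.421 (PGN minus control with streptoc minus LPS) and 0.432 (streptoc minus control with PGN minus LPS).

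The next comparison was streptoc in the carcinoma line. C666-1 cells had higher NRF2 targets with streptoc and no higher NF-kB targets. Of 24 NRF2 targets 5 were higher by 2-fold, with a median of 0.26 (percentile 100). HMOX1, at 8.07 untreated and 10.83 with streptoc, had the highest difference of all genes (2.76). SLC7A11 (1.40), the cystine transporter, and SRXN1 (1.32), which repairs peroxiredoxins, followed. Of the 30 NF-kB targets 0 passed 2-fold in either direction, with a median of -0.05 inside the random lists. CXCL8 differed by 0.16, IL6 by 0.66, IL1B by 0.22, TNF by 0.50, CCL20 by -0.22, NFKBIA by -0.17 and TNFAIP3 by -0.09.

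The ER stress and amino acid response list had 2 of 34 members higher, SLC7A11 and DDIT3 (1.10), and a median of 0.22. CHAC1 differed by 0.76. Of 30 immediate early genes 1 was higher, ATF3 (1.43), with FOSL1 at 0.73 and FOS at 0.63 and a list median of 0.12. Another probe of ATF3 gave 0.36, and FOS was below the filter value on both arrays. Mitosis genes were lower: 32 of 34 lay below the control, 3 by 2-fold, with a median of -0.43. TTK (-1.14), ANLN (-1.04) and BUB1 (-1.03) were lowest, and another probe of BUB1 had the opposite sign. The cornified envelope median of 0.07 was called higher, led by KRT4 (0.82), KLK5 (0.79) and SPRR3 (0.64), and was -0.036 after removal of the expression trend. KRT4 and SPRR3 were below the filter value on both C666-1 arrays. Other genes well above the control were LOC100996756 (1.60), ANKRD37 (1.43), the ribosomal RNA precursor RNA45SN5 (1.33) and the protease PRSS23 (1.20). LOC100996756 was below the filter value in the control (3.83). PRSS23 was below it on both arrays, at 3.57 and 4.77, and another of its probes gave 0.33. The lowest were NECAB1 (-2.39), MICU3 (-1.99), SESN3 (-1.95), SLAIN1 (-1.85), LY75 (-1.75), RGS1 (-1.75), SEC24D (-1.73) and SOX21-AS1 (-1.64). All of these but LY75 and SEC24D were below the filter value with streptoc, at 3.51 (NECAB1) to 4.39 (MICU3).

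In all, 28 genes were higher and 144 lower by 2-fold. With each array centred on its median, a shift of 0.14, the split was 58 higher and 67 lower, and with the mean of all probes it was 12 and 53. After subtraction of the part predicted from the LPS difference in NP69 (slope -0.595), an alternative chosen after seeing the data, it was 50 and 59.

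The streptoc differences of the 2 lines, which share no array, had 7 genes higher by 2-fold in common, where independent lists would share 1.09. Another 23 were higher in NP69 but lower in C666-1, where 5.63 would be shared. Of the genes higher in NP69 with LPS or PGN, 12 (0.97) and 13 (2.42) were also lower in C666-1 with streptoc. The 7 were HMOX1, SLC7A11, SRXN1 and TXNRD1 of the NRF2 list, ATF3, ANKRD37 and the acute phase gene SERPINA3. SERPINA3 and TXNRD1 were named after their values were seen. Another probe of SLC7A11 gave 0.09 in NP69, and other probe values of ATF3 were as low as -0.31 in NP69 and 0.36 in C666-1. GAS1 was lower in both lines (-1.25 and -1.39). In an additive limma model of line and streptoc on these 4 arrays, whose spread is the disagreement of the 2 lines, 1 gene passed the adjusted p threshold and 2-fold, HMOX1, with an effect of 2.48 ± 0.342 (SE, adjusted p = 0.00786, higher in both lines). Without adjustment 159 of the 13430 genes had p below 0.05 in that model, a smaller share than the 0.05 that unchanged genes would give. Across genes the 2 differences correlated negatively, with Pearson's r of -0.435, or -0.377 after removal of the expression trends.

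Among the fixed lists, NF-kB targets had the median furthest from 0 in the difference between the 2 streptoc effects. The list median of the C666-1 effect minus the NP69 effect was -2.08, with 20 of 30 members lower by 2-fold and 1 higher. CXCL8 (-7.47), PTX3 (-6.02), CCL2 (-5.96), CCL20 (-5.67) and CXCL1 (-5.66) were furthest apart. Immediate early genes (median -1, 15 of 30 lower), led by DUSP5 (-2.55), FOSL1 (-2.23) and IER3 (-2.02), and p53 targets (median -0.56, 7 of 24 lower), led by PLK2 (-1.99), PMAIP1 (-1.93) and CDKN1A (-1.5), lay below their random lists. The hypoxia list did so too (median -0.57, ADM -2.33), and that call ended after removal of the expression trends (percentile 5.55). ER stress genes had a median of 0.04 above their random lists, with SESN2 at 0.88, NUPR1 at 0.68 and SLC7A5 at 0.65, and of -0.17 with only the most specific type of probe, an alternative chosen after seeing the data. The median of the simple epithelium and junction list, -0.05, lay above its random lists although it was below 0. PRR15L (2.18), PRICKLE1 (1.92), APLN (1.92), LOC100996756 (1.87) and NCKAP1L (1.86) had the largest differences in the other direction, with another probe of PRICKLE1 at 0.18. Over all genes 524 were higher and 1573 lower, but centring each array turned this split to 1712 and 846, quantile normalization (added after seeing the data) gave 719 and 916, and the mean of all probes gave 261 and 893. The difference between the 2 effects rests on 4 arrays and was not tested.

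**Figure D3:**
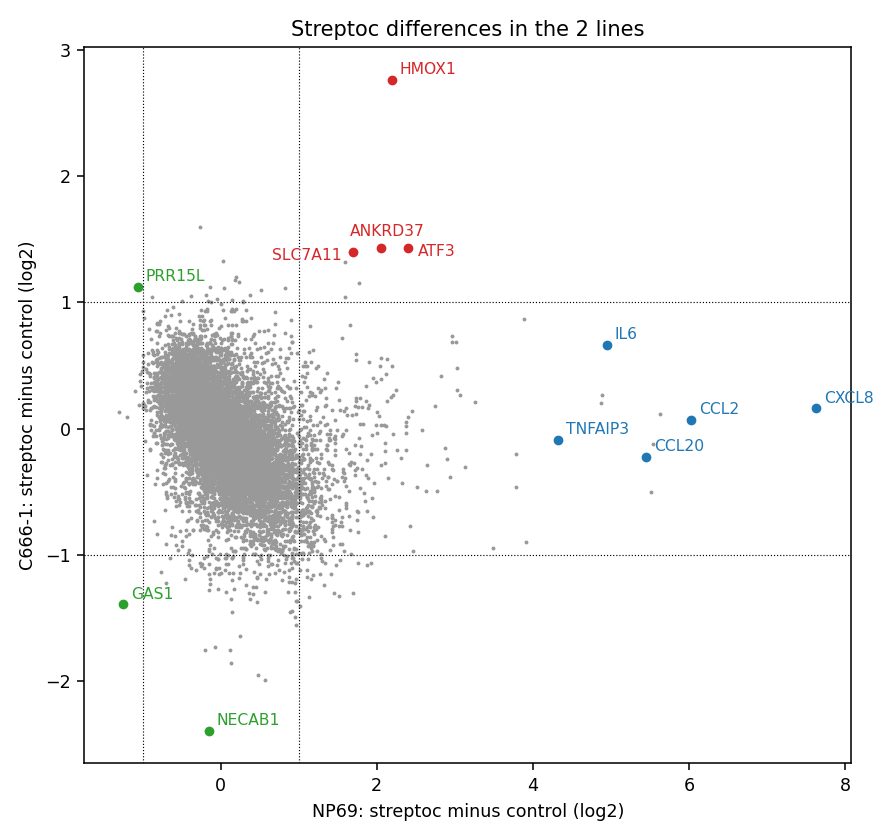
Log2 difference with streptoc in NP69 (x axis) and in C666-1 (y axis) for the 13430 compared genes, 1 point per gene, with 2-fold marked by dotted lines. By the probe used for each gene, HMOX1, SLC7A11, ANKRD37 and ATF3 are past 2-fold in both lines. CXCL8, CCL2, CCL20, IL6 and TNFAIP3 are 4.32 to 7.63 higher in NP69 and between -0.22 and 0.66 in C666-1.

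Without treatment, the 2 lines differed in epithelial identity, antigen presentation and inflammatory genes. Of 20 basal squamous epithelium genes 15 were lower by 2-fold in C666-1 and 0 higher, with a median of -1.89. The basal keratins KRT14 and KRT5 differed by -7.82 and -6.85 and the calcium-binding protein S100A2 by -7.35. Of 27 cornified envelope genes 19 were lower and 2 higher, with a median of -2.59 and SERPINB3 (-6.48), KRT4 (-6.09, or -0.64 by another probe) and CSTA (-5.30) lowest. Of 13 MHC class II genes, which present antigen to helper T cells, 10 were higher in C666-1 and 0 lower, with a median of 4.51. HLA-DRA (6.02), HLA-DPA1 (6) and the protease CTSS (5.40) were highest.

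The NF-kB list was already high in untreated C666-1, with 18 of 30 members above untreated NP69 by 2-fold, 2 below and a median of 1.90. CCL20 was 13.25 against 5.32, and PTGS2, the inducible prostaglandin synthase, and CCL5 differed by 7.49 and 6.74. CXCL8 differed by 0.15. Of 24 p53 targets 14 were higher and 1 lower (median 1.55), with DDB2 (4.32), GDF15 (3.71) and the death receptor FAS (3.49) highest. Of 26 pattern recognition receptors and adaptors 8 were higher and 2 lower (median 0.58), led by the inflammasome adaptor PYCARD (6.22), TLR1 (3.64) and TLR5 (2.35). Without the filter that median was -0.02.

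Several lists were lower in C666-1. Mitosis genes had a median of -0.81, with 12 of 34 lower, including CCNB1 (-2.36), KIF20A (-2.24) and CDC20 (-2.01). Interferon-stimulated genes had 13 of 37 lower and 6 higher (median -0.56), with RSAD2 (-3.71), IFI27 (-3.68) and HERC5 (-3.67) lowest. Mesenchymal and matrix genes (median -0.69) were split, with 9 of 25 lower and 7 higher, and included THBS1 (-7.49), TGFBI (-6.91) and TWIST1 (-4.33), although VIM, the mesenchymal filament protein, was 2.89 higher. Antimicrobial and secretory genes had a median of -0.58, with 7 of 19 lower, among them SLPI (-6.38), MUC1 (-3.58) and PI3 (-3.33), and 2 higher, S100A8 (2.52) and WFDC2 (2.78), chosen after their values were seen. Genes reported silenced or lost in nasopharyngeal carcinoma had 5 of 15 lower and 2 higher (median -0.45), with the Wnt antagonist SFRP1 (-6.74), TGFBR2 (-5.58) and CDKN2A (-3.83) lowest. With the stricter filter that median was 0.05, and after removal of the expression trend it lay inside the random lists (percentile 14.34). Among epithelial markers CDH1 differed by -3.14, KRT19 by -1.05 and EPCAM by 1.51.

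Over all genes 2120 were higher and 1080 lower in untreated C666-1. The highest were VCAM1 (8.03), CCL20 (7.93), the neuroendocrine factor INSM1 (7.58), PTGS2, LRRN1 (7.37), the neurotrophin receptor NTRK2 (7.33), ID2 (7.25) and DCLK1 (7.05). The lowest were FABP5 (-9.40), MGST1 (-8.45, or -1.12 by another probe), EFEMP1 (-8.24), AQP3 (-8.13), CAV1 (-7.95), KRT14, ALDH1A3 (-7.68) and STOM (-7.52). Another probe of NTRK2 gave 0.05. In limma over all 6 arrays by line, with treatment differences counted as spread, 1407 genes were higher and 1292 lower past 2-fold and the adjusted p threshold. With each array centred on its median, a shift of -0.17, the split of the 2 control arrays was 1740 and 1437, and the C666-1 control array against the NP69 LPS array, chosen after seeing the data for its like spread of values and differing in treatment as well, gave 1644 and 1229.

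With streptoc on both lines, the comparison was repeated on the other arrays of each line. Past 2-fold, 1000 genes were higher and 921 lower in C666-1 in both comparisons, where independent lists would share 184.22 and 143.95. Basal squamous genes (median -2.42, 17 of 20 lower), cornified envelope genes (-2.73, 18 of 27 lower) and mitosis genes (-1.21, 24 of 34 lower) were lower, and MHC class II genes (4.15, 10 of 13 higher) and p53 targets (0.64, 9 of 24 higher) were higher. KRT14 (-7.72), S100A2 (-7.35), KRT5 (-7.20), SERPINB3 (-7.37), KRTDAP (-6.06) and SPRR1B (-6.05) were among the low epithelial genes. HLA-DRA (6.72), HLA-DPA1 (5.92), HLA-DRB1 (5.76), DDB2 (3.78) and GDF15 (3.19) were among the high ones.

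Of the lists called in the untreated lines, 4 did not keep their call. Pattern recognition (median 0.40), antimicrobial (0.21) and mesenchymal genes (0.08) lay inside their random lists. Past 2-fold, antimicrobial genes still had 2 higher and 7 lower, as untreated. Mesenchymal genes had 6 higher and 10 lower, against 7 and 9 untreated, and pattern recognition genes 6 and 4, against 8 and 2. For the first 2 of these lists the lost call thus reflects the median and not the members past 2-fold. NF-kB targets had the opposite direction. With streptoc the list median was -0.36, with 9 members higher and 11 lower in C666-1, and CXCL8 (-7.32), CXCL2 (-7.07) and CXCL1 (-6.21) lowest, while PTGS2 (7.43) and CCL5 (6.72) stayed high. After removal of the expression trend this list lay inside its random lists (percentile 4.65). There were 18 genes past 2-fold in opposite directions, each higher in C666-1 untreated and lower with streptoc, among them CCL2 (3.48 and -2.48) and CXCL3 (3.65 and -1.16), chosen after their values were seen. Interferon-stimulated genes (median -0.81, CMPK2 -4.78) and carcinoma-silenced genes (median -0.97, or 0.08 without the filter, SFRP1 -5.79) were lower, and ER stress genes (median 0.29, VLDLR 3.66, DDIT3 2.35) higher. The cholesterol synthesis list, which also holds the fatty acid genes FASN and FADS2, had a median of -0.52. FDPS was at -1.80, FASN at -1.57 and FADS2 at -1.55, and other probes of FASN and FADS2 had the opposite sign. VIM (2.66), CDH1 (-3.63), KRT19 (-0.95) and CDKN2A (-3.64) stayed close to their untreated differences, and EPCAM was 0.28.

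Over all genes 1167 were higher and 1790 lower. TEX19 (7.24), VCAM1 (7.18), NTRK2 (7.39), DCLK1 (7.27) and ROBO1 (6.65) were among the highest, and FABP5 (-9.40), ALDH1A3 (-8.35), MGST1 (-8.13), AQP3 (-8.12), CYP1B1 (-8.08), STEAP4 (-7.99), THBS1 (-7.95) and CAV1 (-7.84) were lowest. Another probe of CYP1B1 gave -0.56. With each array centred on its median, a shift of 0.15, the split was 1467 and 1474. The C666-1 streptoc array against the NP69 control array, chosen after seeing the data for its like spread and differing in treatment as well, gave 1540 higher and 1247 lower. Across genes the 2 differences between the lines correlated with Pearson's r of 0.812.

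**Figure D4:**
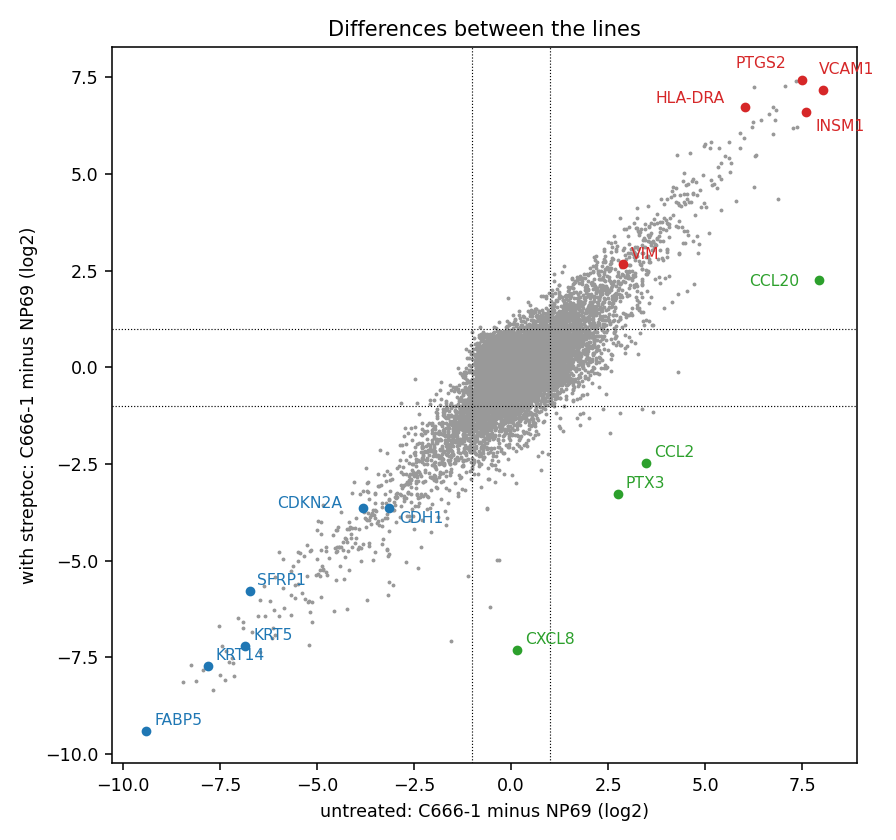
Log2 difference of C666-1 minus NP69 in untreated cells (x axis) and with streptoc (y axis), 1 point per compared gene, with 2-fold marked by dotted lines. FABP5, KRT14, KRT5, SFRP1, CDKN2A and CDH1 are low and VCAM1, PTGS2, INSM1, HLA-DRA and VIM high in both, whereas CXCL8 moves from 0.15 to -7.32 and CCL20 from 7.93 to 2.26.

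The other lists were called in no comparison on the values as deposited, with the simple epithelium and junction list outside its random lists in the difference of the effects as given above. After removal of the expression trend, simple epithelium genes were called higher with LPS (percentile 98.09) and between the lines with streptoc (98.25), and ribosomal protein genes higher with PGN (97.54) and streptoc (97.83) in NP69 and lower in the difference of the effects (2.42). In the untreated lines the medians were -0.01 for MHC class I genes, -0.06 for oxidative phosphorylation genes, 0.12 for cytosolic ribosomal protein genes, 0.37 for simple epithelium and junction genes, -0.21 for Wnt targets and -0.48 for 6 measured cancer-testis antigen genes. Markers of other cell types had medians of -0.31 (8 ciliated cell genes), -0.11 (11 leukocyte genes) and -0.20 (8 endothelial genes). Of the 11 leukocyte genes 3 were 2-fold higher in C666-1 and 0 lower, untreated and again with streptoc, as were MHC class II genes. They were LCP1 (6.43 untreated), ITGAM (4.63) and LAPTM5 (2.42), chosen after their values were seen. Of 196 list medians, 32 were called higher and 25 lower, and 49 of the 57 kept their call after removal of the expression trend, which also gave 9 calls more. The share of 5% outside the percentiles would be 9.8 for independent lists, which these are not, since list members vary together and the comparisons share arrays. Of 91 named differences past 2-fold with over 1 probe past the filter, 35 had another probe short of 2-fold in that direction, 8 of them with the opposite sign.

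**Figure D5:**
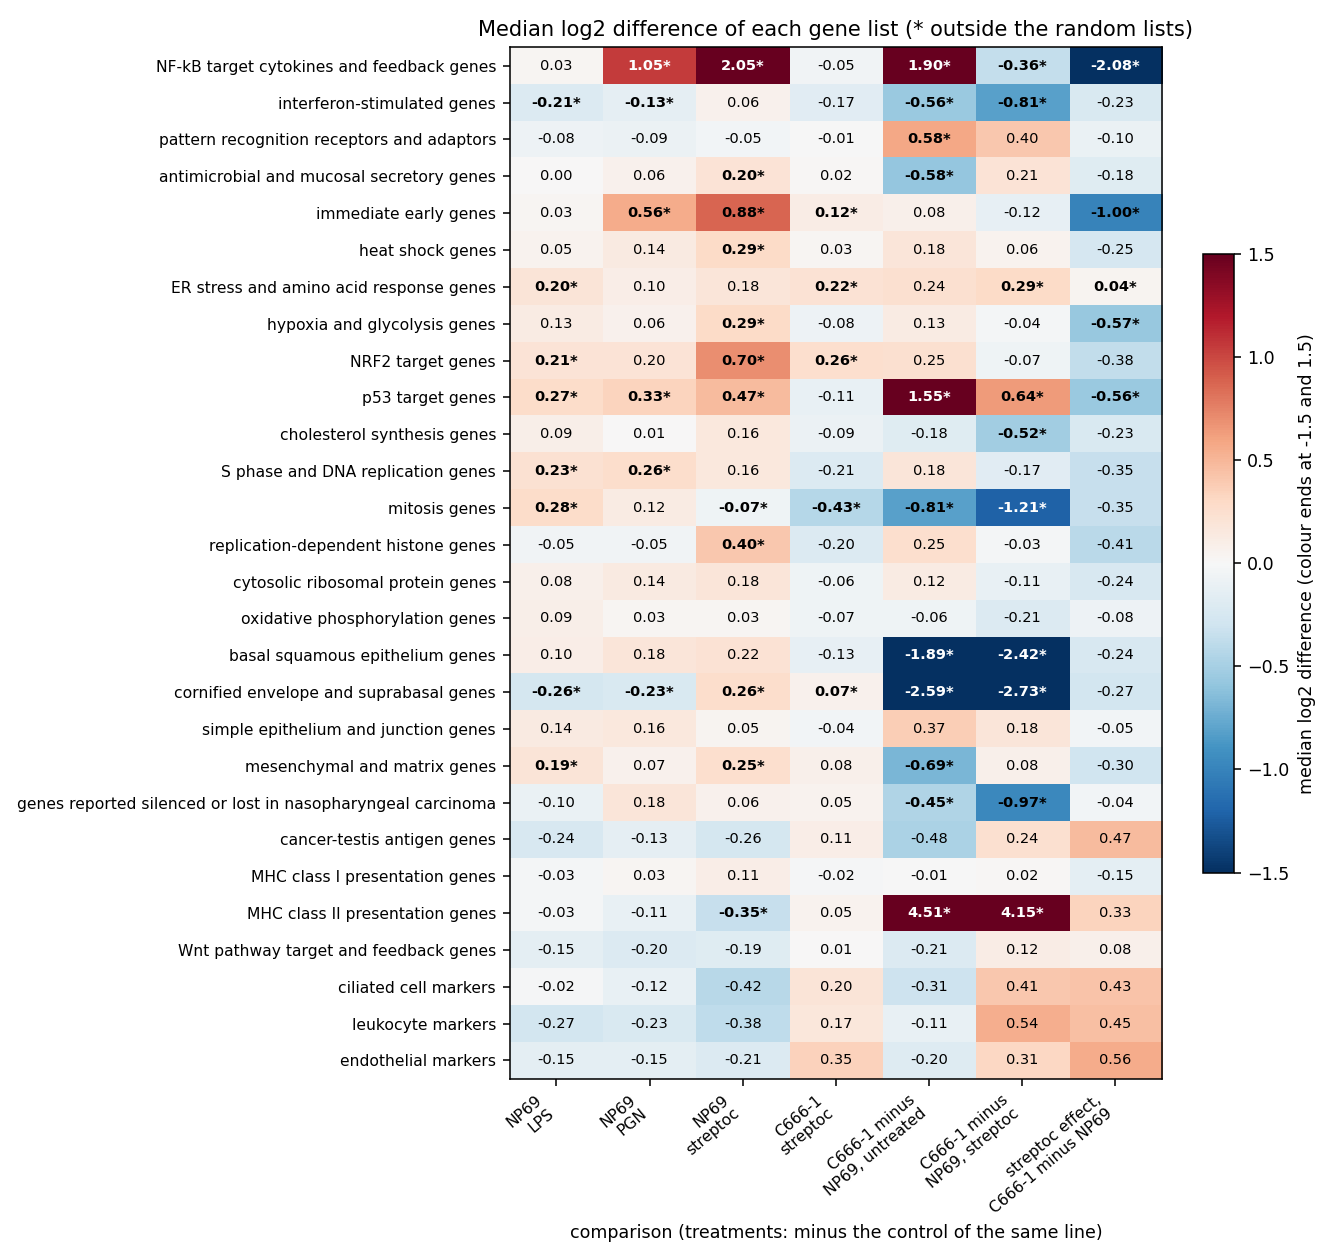
Median log2 difference of each of the 28 gene lists (y axis) in the 7 comparisons (x axis), with colour from -1.5 to 1.5 and values with an asterisk in the outer 5% of 10000 random lists. NF-kB targets read 0.03, 1.05 and 2.05 with LPS, PGN and streptoc in NP69 and -0.05 with streptoc in C666-1, and NRF2 targets 0.70 and 0.26 with streptoc in the 2 lines.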

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

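The 2 gene length tests were chosen before their results were seen, and all other tests of this part only after, with those of the interferon-stimulated and cornified envelope genes replacing earlier ones whose outcome was known.

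With streptoc, 23 genes were 2-fold higher in NP69 and 2-fold lower in C666-1 (5.63 in independent lists). For genes higher in NP69 with LPS or PGN, the overlap with genes lower in C666-1 with streptoc was 12 (0.97) and 13 (2.42). The pattern was not particular to streptoc in NP69, but the 3 overlaps used the same NP69 control array and the same C666-1 arrays. They also shared genes, among them DMXL2, ERBIN, HELLS and RCBTB1, and are not separate observations. With streptoc 1 gene, PRR15L, chosen after its values were seen, was lower in NP69 and higher in C666-1. These differences between the lines were not tested. Probes without a single gene name, which entered no comparison, were also 2-fold above the control: 35 with LPS, 55 with PGN, 119 with streptoc in NP69 and 3 with streptoc in C666-1, of 4261 such probes past the filter. The numbers 2-fold below the control were 0, 1, 5 and 36 in the same order.

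Across genes, the NP69 treatments and C666-1 with streptoc differed from their controls in opposite directions. Scaling that depends on intensity was not the whole cause, since the correlation of the LPS and C666-1 streptoc differences was -0.482 after the loess curves were removed, and -0.452 after gene length was removed as well. Gene length may have had a part, since Spearman's rho of genomic length with the loess-corrected difference was -0.282 in C666-1 and 0.203 with LPS. The 90 genes higher with LPS had a median of -0.685 in C666-1 with streptoc, which follows from that correlation and decides nothing. An RNA or labelling state shared by the NP69 control and C666-1 streptoc arrays and opposite responses of the lines cannot be told apart with 1 array per group.

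NF-kB targets were higher with streptoc in NP69 and not in C666-1. For 9 of the 19 members 2-fold higher in NP69, untreated C666-1 was at least 1 below NP69 with streptoc, and their median difference in C666-1 was 0.12, which argues against an array ceiling for them. Of the other 10, 8 lay at 6.35 to 10.17 in untreated C666-1, at least 4.07 below the highest value of that array, which argues against an array-wide ceiling but not against saturation of single probes, while CCL20 and NFKBIA, in its highest 1% and as close as 0.99, leave both open. Median differences by expression group in C666-1 with streptoc lay between 0.16 and -0.19. A trend of this size, from the narrower range of that array, is too small to hide a rise like the NP69 list median of 2.05. The list median of 0.041 after the loess curve was removed was bound to stay small and adds no test. A pathway already active in untreated C666-1, or a weaker response of this line, might also give the pattern, and neither was tested.

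Interferon-stimulated and cornified envelope genes were lower with LPS and PGN than in the NP69 control. The narrower range of the control array is argued against by LPS medians of -0.27 and -0.287 after the loess curve was removed. A high control array with no effect of streptoc is argued against by medians of streptoc minus LPS of 0.33 (31 of 37 members higher) and 0.38 (19 of 27). A high control array together with a streptoc effect on these genes could still give the pattern, as could lower expression with LPS and PGN, and both stay open with 1 control array.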

How the results depend on the processing

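Chosen only after the data were seen were quantile normalization, the choice of probe type, the LPS array as reference, the regression on the LPS difference and the line comparisons between arrays of like spread. Of 79 total counts and correlations under alternatives, 57 moved little (counts within 1.5 times) and 22 moved. Totals hide the split of higher and lower genes. With LPS it turned from 90 and 6 to 0 and 38 against the mean of the other 3 NP69 arrays, a changed comparison since that mean includes PGN and streptoc. Centring turned it from 524 and 1573 to 1712 and 846 in the difference of the effects. For C666-1 with streptoc it turned from 1167 and 1790 to 1540 and 1247 when NP69 with streptoc was replaced by the NP69 control. That replacement changes treatment and spread together. Of 1372 list medians 578 moved and 7 reversed, and of 1897 values of named genes 105 moved and 2 reversed. Only medians of called lists and named genes past 2-fold could be counted as reversed. Other changes of sign were not counted apart.

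The 1.5-fold threshold gave 975 genes with LPS, 1307 with PGN and 2332 with streptoc in NP69, 1393 with streptoc in C666-1, 5790 between the untreated lines, 5425 between the lines with streptoc and 5507 for the difference of the streptoc effects, as a lower threshold must give more. Centring the arrays gave 55 genes with LPS. The mean of all probes gave 31 with LPS, 116 with PGN, 284 with streptoc in NP69, 65 with streptoc in C666-1 and 1154 for the difference of the effects. The mean of the other 3 NP69 arrays as reference gave 38 with LPS, 17 with PGN and 194 with streptoc, and the LPS array as reference 46 with PGN and 224 with streptoc. Subtraction of the regression on the LPS difference gave 109 in C666-1. The additive limma model gave 1 gene for NP69 streptoc and 1 for C666-1 streptoc, as it is a single streptoc term for both lines. With the filter at the 75th percentile the correlation of the 2 streptoc differences was -0.3.

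Without the filter, the medians reversed to -0.02 for pattern recognition genes in the untreated lines, -0.05 for mesenchymal genes with LPS and -0.05 with streptoc in NP69, and 0.08 for carcinoma-silenced genes between the lines with streptoc. With the filter at the 75th percentile that list had 0.05 in the untreated lines. After subtraction of the loess curve, cornified envelope genes had -0.036 in C666-1 with streptoc. With only probes of the unmarked type, ER stress genes had -0.17 in the difference of the effects, ATF3 had -0.31 in NP69 with streptoc and FADS2 had 0.01 between the lines with streptoc. Apart from the threshold, the limma model and the changes of reference, which alter the comparison itself, the cause was not tested. The labels give no replicate numbers to pair by, and the additive limma model compares streptoc with control within each line. The filter value of 4.92 is the median of all values of the probes used. No background level was measured, and differences that involve values below the filter may be compressed.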

Other observations

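The genes of this part, apart from PYCARD, were chosen after their values were seen. Levels of a few receptors are given here without a count or test over all of them, and NOD1 (6.64 and 6.56 in untreated NP69 and C666-1) and TLR9 (4.96 and 4.69) were close in the 2 lines. TLR2 was 6.47 in the NP69 control, 7.15 with PGN and 7.72 with streptoc, and 5.35 and 5.67 in C666-1 without and with streptoc. LY96, the partner of TLR4 in lipopolysaccharide binding, was 2.90 in the NP69 control (percentile 10.7 of that array) and 5.13 in untreated C666-1. TLR4 was 4.98 and 4.26 in the 2 untreated lines, and CD14, at 4.74 and 4.31, did not pass the filter. The adaptor MYD88 was 8.71 and 9.78.

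The list of receptors and adaptors as a whole lay inside its random lists with streptoc in NP69, with 3 of 26 members 2-fold higher and a median of -0.05. Of these 3, IRAK2 was 5.20 in the control and 7.58 with streptoc, and NOD2 was 4.49 and 5.56, while in C666-1 IRAK2 was 5.82 and 5.84 and NOD2 4.10 and 4.47. Of the inflammasome genes, PYCARD was 5.07 in untreated NP69 and 11.29 in untreated C666-1, and CASP1 was 8.41 and 4.46.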
